A study of Mus musculus with 8 samples.

How the data were processed

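The data were H3K27me3 chromatin immunoprecipitation sequencing (ChIP-seq) libraries from livers of male CD-1 mice, an outbred stock, aged 7 weeks. Per the labels, mice received TCPOBOP at 3 mg/kg or the vehicle, 1% DMSO in corn oil, and livers were taken 3 h later. Chromatin came from individual livers, so the replicates of a group were separate animals. The 600 to 1100 bp fragments of each ChIP sample were digested to 500 bp before sequencing, giving 3 vehicle and 3 TCPOBOP libraries. For 1 vehicle and 1 TCPOBOP ChIP sample, replicate 1 of each group, a further library was made from fragments over 1100 bp digested to 200 bp. The label text placed all 8 libraries on the same flow cell lane.

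Each library came as a list of islands with a score per island, and the submitters' processing notes name Bowtie2 2.3.2, SICER 1.1 and the mouse build mm9 without giving their roles. The deposited score is the authors' own value for each island, relative to a background modelled for that library. Scores as such were therefore used to describe, rank or filter islands within a list, apart from the uses that follow. A score minimum was applied across lists as an alternative. Scores were turned into reads relative to each library's background to compare 1 island on chromosome 2 between livers. At Cyp2b10 an island's score was set beside the lowest scores of other lists. The file names carry a window of 400 bp and a gap of 2400 bp, and the island ends fell on that 400 bp grid with a smallest gap of 2800 bp between listed islands. Islands were called on each library separately, not on pooled replicates. Use of an input library is not given in the sources used here, and no input was analysed here. Coordinates are mm9 and 1-based.

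The lists hold no read counts. The mean number of background reads per 400 bp window was worked out from the scores, taking a window's score as the negative natural logarithm of its Poisson probability and the window threshold as the lowest whole number of reads with a Poisson tail of 0.2 or less. These forms were assumed from general knowledge of the caller and are not stated in the labels. For the 600 to 1100 bp lists the background was the value whose steps matched the most differences between scores. That method was tested on simulated data and recovered the background in 3 of 3 simulated lists. The simulated islands held fewer windows than most islands of the real lists, so recovery at the real widths was not tested. For the 2 lists of fragments over 1100 bp it was solved from the narrowest islands, as the value that left the smallest misfit in the next island (5.02e-09 and 4.37e-09, against 1.34e-05 and 2.34e-04 for the next best value). That method was not tested on simulated data, and the depth of these 2 libraries, their place in the ranking by background share and their chromosome 2 values rest on it. Vehicle replicate 1 had the fewest matched score steps, 74 against 21 for the next best value. TCPOBOP replicates 2 and 3 had 483 against 167 and 230 against 58. These 3 are the libraries with the higher background share, so the split by that share rests on the weaker matches. Vehicle replicates 2 and 3 and TCPOBOP replicate 1 had 2638 against 192, 5035 against 973 and 4477 against 398. Total reads per library remained unknown, so no counting interval was computed.

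Covered length was the length under islands, given also as a percent of the mm9 chromosomes. Islands of the 6 libraries of 600 to 1100 bp were merged into union regions. A region was present in a library when at least 50% of its length lay under islands and absent when 0% did. The Jaccard index was the length covered in both libraries divided by the length covered in either. Number, covered length, median width and the covered percent of locus windows were compared with two-sided exact permutation tests of the difference of means, over 20 labellings. With 3 livers against 3 the smallest p these tests can give is 0.1, so none could pass 0.05. The covered fraction of regions at 50% or more in at least 2 libraries was tested with limma 3.58.1 in R 4.3.3, with a trend and Benjamini-Hochberg adjustment at 0.05. On simulated data for this comparison with 8659 regions, limma recovered 4 of 100 regions changed by 0.5 of their length and 55 of 100 changed over their whole length, with 1 false call. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

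The main tests, most alternatives and the rule for named regions were fixed before the data were examined. Under that rule the text could name the 5 longest regions present in all 6 libraries, the 5 highest-scoring islands of each list found in all 6, the 5 longest regions per direction present in 1 treatment alone, the 5 limma regions with the smallest p, and 7 locus windows. The 7 windows were approximate mm9 positions taken from general knowledge, so their edges do not follow an annotation. The gene table in use was of assembly GRCm38.p6, not mm9, and served only for gene names and gene order. For that reason the planned count of marked promoters by gene list, and all alternatives to it, were not run, and genes near other regions are not named. Alternatives covered leaving out each liver, a score minimum of 101 taken as the median of the pooled 6 lists, equal covered length by keeping the highest-scoring islands up to 174 Mb (up to the length of the shorter list for the 2 libraries of a ChIP sample), autosomes only, the union of both libraries of a ChIP sample, other presence rules, 10 kb bins, and for limma a replicate block, an arcsine square root scale, centring and no filter. Further alternatives were added after the data had been seen and are named as such where they are used.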

Results

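H3K27me3, the histone mark laid down by Polycomb repressive complex 2, was profiled in livers of male CD-1 mice 3 h after TCPOBOP or vehicle. TCPOBOP is an agonist of the nuclear receptor CAR, which induces drug-metabolising enzymes such as Cyp2b10. The 600 to 1100 bp fragments gave 3 vehicle and 3 TCPOBOP libraries from 6 livers, and fragments over 1100 bp gave 1 library per treatment from the ChIP samples of replicate 1. The 6 libraries of 600 to 1100 bp listed 6295 to 14748 islands covering 174 to 340 Mb, or 6.56 to 12.8% of the mm9 chromosomes. Their background, worked out from the island scores, was 2.40 to 3.26 reads per 400 bp window. The libraries of fragments over 1100 bp were deeper, at 14.2 and 14.5 reads per window.

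The Hox clusters, which hold homeobox genes that pattern the embryonic axis and are classical Polycomb targets, lay under islands in both treatments. The HoxA window was 100% covered in all 8 libraries, and the island over it ranked between 1 and 6 by score in each list. HoxC was 97.3 to 100% covered and HoxD 97.1 to 100% in the 8 libraries. HoxB was 77.8 to 100% covered in the 6 libraries of 600 to 1100 bp. Both lists of fragments over 1100 bp showed no island for about 490 kb around HoxB, while the 600 to 1100 bp libraries of the same ChIP samples were 100 and 96.4% covered. Rows of those 2 lists may be missing here, so HoxB was not analysed in them and the gap is not read as absence of the mark. In the GRCm38.p6 gene order these clusters hold 11, 10, 9 and 9 Hox genes from HoxA to HoxD, with no other protein-coding gene inside any of the clusters. The window over Alb and Afp, which encode serum albumin, a main product of hepatocytes, and alpha-fetoprotein, lay under no island in any of the 8 libraries.

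Of the regions present in all 6 livers, the longest spanned 693 kb on chromosome 8, from 11937201 to 12630400, and was 81.9 to 99.8% covered in every library of 600 to 1100 bp. It was followed by regions of 465 kb on chromosome 4 (139614001 to 140078800) and 408 kb on chromosome 11 (95972801 to 96380400), the latter over the HoxB window. A dense island of 27.6 kb on chromosome 2, from 77808001 to 77835600, had the same start and end in all 8 lists and ranked between 2 and 6 by score per kb in each. Coverage of the autosomes was uneven, from 19.3% of chromosome 11 to 6.27% of chromosome 3 as vehicle means. Chromosome X held 1 to 37 islands per library of 600 to 1100 bp, which covered 0.0163 to 0.228% of it, against 7.04 to 13.7% of the autosomes. Male cells carry fewer copies of X than of each autosome, so this is not read as absence of the mark.

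The first comparison asked whether TCPOBOP altered the amount of H3K27me3 territory within 3 h. Vehicle livers had 12412 ± 2346 islands (SD, n = 3) and TCPOBOP livers 10084 ± 3733 (SD, n = 3), a difference of -2328 (exact permutation p = 0.5). Islands covered 274 ± 72.7 Mb with vehicle and 234 ± 54.3 Mb with TCPOBOP (SD, n = 3 each, exact permutation p = 0.4). Median island width was 18.3 ± 7.49 kb with vehicle and 20.5 ± 5.37 kb with TCPOBOP (SD, n = 3 each, exact permutation p = 0.9). Each of these differences was smaller than the spread between livers of a treatment, and the smallest p the design allows is 0.1. The difference in island number was -4166 without TCPOBOP replicate 1, -434 without TCPOBOP replicate 3, -3505 and -1160 without vehicle replicates 1 and 2, and -1095 with the score minimum. That in covered length, -39.5 Mb, was -78.2 Mb without vehicle replicate 3, -6.20 Mb without vehicle replicate 1, -62.4 and -9.50 Mb without TCPOBOP replicates 2 and 3, and -8.86 Mb with both libraries of a ChIP sample merged. Width ranked the libraries by their background and not by treatment. In vehicle replicate 1 and TCPOBOP replicates 2 and 3, where 16.4 to 18.6% of background windows reached the read threshold, median widths were 26.80, 22.8 and 24.4 kb. In vehicle replicates 2 and 3 and TCPOBOP replicate 1, at 9.56 to 11.2%, they were 15.2, 12.8 and 14.4 kb. Among the 3 libraries with the higher share, islands covered 340 Mb with vehicle and 280 and 174 Mb with TCPOBOP. Among the 3 with the lower share they covered 284 and 196 Mb with vehicle and 248 Mb with TCPOBOP.

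**Figure D1:**
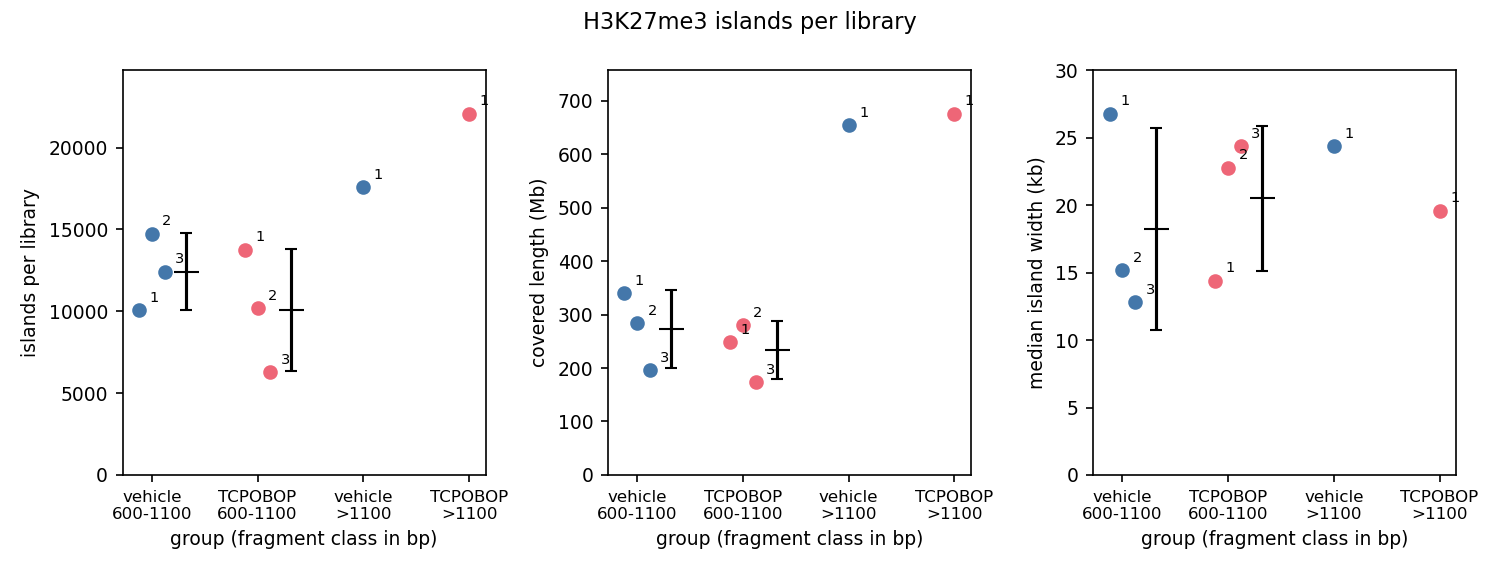
Number of islands, covered length (Mb) and median island width (kb) of each of the 8 libraries, as points numbered by replicate; blue is vehicle, red is TCPOBOP, and bars give the mean and SD of the 3 libraries of 600 to 1100 bp per treatment. The treatments overlap in all 3 measures, and the 2 libraries of fragments over 1100 bp cover 654 and 676 Mb.

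**Figure D2:**
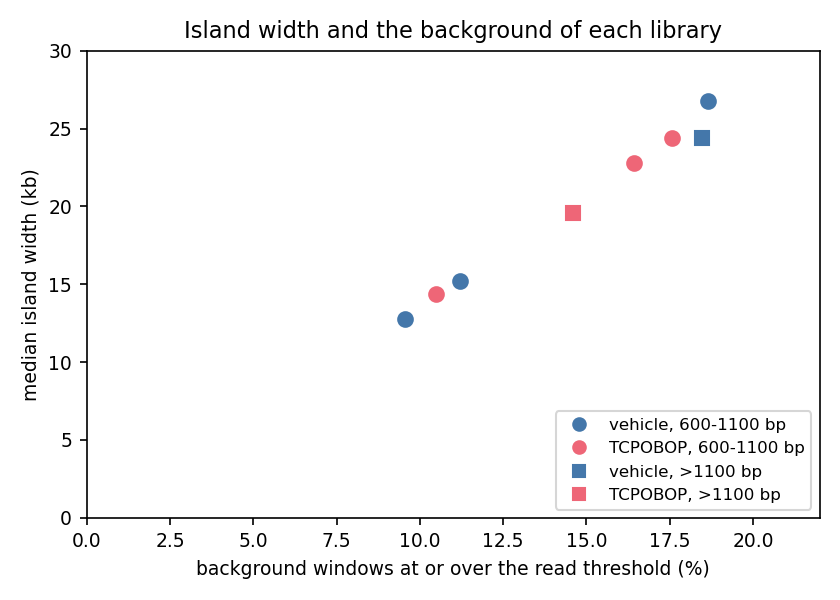
Median island width (kb) against the percent of background windows that reach the read threshold of the island caller, 1 point per library, with circles for 600 to 1100 bp and squares for fragments over 1100 bp. Widths run from 12.8 kb at 9.56% to 26.80 kb at 18.6%, with both treatments at each end.

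Livers of the same treatment shared no more territory than livers of different treatments. The mean Jaccard index was 0.405 over 6 pairs of the same treatment and 0.411 over 9 pairs of different treatments (difference -0.0064, exact permutation p = 0.6 over 10 splits). Independent placement would have given about 0.049. Of 537 Mb covered in any of the 6 livers, 64.7 Mb (12.1%) was covered in all 6 and 174 Mb (32.4%) in 1 alone. Of 14560 union regions, 843 were present in all 6 livers by the 50% rule. The direction turned to 0.0157 and 0.0162 without TCPOBOP replicate 1 or 2, and the difference was -0.0643 with both libraries of a ChIP sample merged. The merge added lists of 654 and 676 Mb to replicate 1 of each treatment alone, and these lists shared a Jaccard index of 0.764. That value is therefore not on equal terms with the others.

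**Figure D3:**
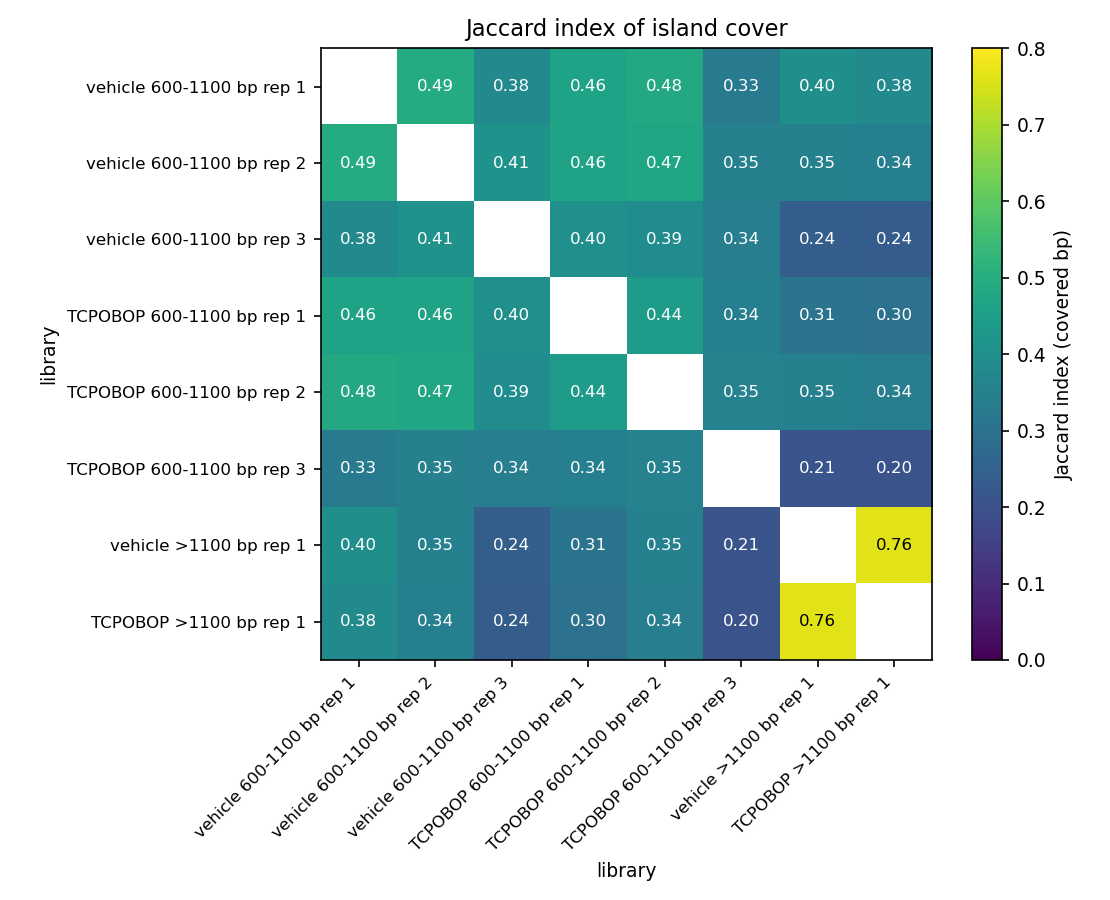
Jaccard index of covered length for each pair of the 8 libraries, printed in each cell and coloured from 0 to 0.8. Pairs within and between treatments in the class of 600 to 1100 bp range alike from 0.333 to 0.494, and the 2 libraries of fragments over 1100 bp share 0.764.

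At the level of single regions, 38 were present in all 3 vehicle livers and absent from all 3 TCPOBOP livers, and 7 showed the opposite. The 38 regions had a median width of 19.2 kb and the 7 regions 25.6 kb. The longest of the first kind were 33.2 kb on chromosome 9 (20330801 to 20364000), 80.7 to 88.0% covered in the vehicle livers, and 33.2 kb on chromosome 19 (12482801 to 12516000), 66.3 to 85.5% covered. The longest of the second kind were 30 kb on chromosome 7 (88257201 to 88287200), 53.3 to 92.0% covered in the TCPOBOP livers, and 29.2 kb on chromosome 11 (26688801 to 26718000), 53.4 to 98.6% covered. With all lists cut to an equal covered length, 1 region was specific to vehicle and 9 to TCPOBOP, so the direction of the imbalance was not kept. Without TCPOBOP replicate 3 there were 46 specific to vehicle and 111 to TCPOBOP. That setting asks for presence in fewer TCPOBOP livers but still in all 3 vehicle livers, so these counts are not on equal terms. The other 9 splits of the 6 livers gave 19 to 102 such regions, against 45 for the treatments.

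Using limma on the covered fraction of 8659 regions, 0 regions were higher and 0 lower with TCPOBOP at an adjusted p of 0.05, and 225 had an unadjusted p under 0.05. Of these 225, 31 were higher and 194 lower, a split that became 238 higher and 145 lower after centring each library. The smallest p belonged to a 6.0 kb region on chromosome 3 (69449601 to 69455600), 93.3, 100 and 100% covered in the vehicle livers. In the 3 TCPOBOP livers 0% of it was covered (difference of means -97.8 percentage points, limma SE 28.8, limma adjusted p = 1). That SE came mainly from limma's variance trend over all regions, so it does not measure the spread of these livers. On the arcsine scale limma called 1 region, 6.8 kb on chromosome 3 (25039201 to 25046000), at an adjusted p of 0.043. It was 94.1 to 100% covered in the vehicle livers and 94.1, 0 and 0% in the TCPOBOP livers. TCPOBOP replicate 1 was thus covered as much as vehicle replicate 2. The arcsine fit used the same kind of variance trend, so its p is not read as a measure of the spread of these livers. Regions changed by 0.5 of their length were recovered in 4 of 100 simulated cases, so most changes of that size were not detectable with these lists. The 6.0 kb region on chromosome 3, changed over nearly its whole length, was not called either. The simulated recovery of whole-length changes therefore may not carry over to these lists. The 0 calls do not show that regions kept their cover.

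Cyp2b10, the cytochrome P450 gene classically induced through CAR, was covered in part in each of the 6 livers. In its 50 kb window (chromosome 7, 26670001 to 26720000), islands covered 48.0, 40.0 and 38.4% in the vehicle livers and 32.8, 20 and 19.2% in the TCPOBOP livers. The means were 42.1 ± 5.14% and 24.0 ± 7.63% (SD, n = 3 each), a difference of -18.1 percentage points with no overlap between treatments (exact permutation p = 0.1, the smallest possible; adjusted over 7 windows 0.7). Chance alone separates 3 livers from 3 in 10% of such comparisons. A stretch of 7.6 kb from 26691601 to 26699200 lay under islands in all 6 livers. A stretch of 4.4 kb from 26705201 to 26709600 did so in 3 of 3 vehicle and 0 of 3 TCPOBOP livers. By score, the islands over the 4.4 kb stretch ranked 2834 of 10057, 8488 of 14748 and 12248 of 12430 in vehicle replicates 1, 2 and 3. That of vehicle replicate 3 scored 41.4, while the lowest score in any TCPOBOP list was 44.2, in replicate 1. The contrast at this stretch is therefore not told apart from differences in the lowest score that each list holds. Among the 3 libraries with the higher background share the values were 48.0% for vehicle and 20 and 19.2% for TCPOBOP, and among the 3 with the lower 40.0 and 38.4% and 32.8%, an order that groups without overlap keep in any subset. At equal covered length the treatments overlapped, with 48.0, 19.2 and 19.2% for vehicle and 0, 20 and 19.2% for TCPOBOP (difference -15.7 percentage points, exact permutation p = 0.6). They also overlapped with the score minimum, at 48.0, 19.2 and 19.2% against 0, 20 and 0% (difference -22.1, exact permutation p = 0.3). The lists of fragments over 1100 bp covered 15.2% of the window in the vehicle liver and 0% in the TCPOBOP liver. Rows of these lists may be missing, as around HoxB, so the 0% is not read as absence of the mark.

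The neighbouring window around Cyp2b9 and Cyp2b13, related P450 genes with higher expression in female than in male mouse liver, was covered to 24.2 ± 7.39% with vehicle and 9.83 ± 9.21% with TCPOBOP (SD, n = 3 each, exact permutation p = 0.2). Livers overlapped, with 22.5, 32.3 and 17.8% for vehicle and 0, 18.3 and 11.3% for TCPOBOP. With the score minimum they did not overlap, at 22.5, 32.3 and 11.5% against 0, 8.5 and 0% (exact permutation p = 0.1). At equal covered length the values were 0, 32.3 and 17.8% against 0, 0 and 11.3% (exact permutation p = 0.4). The difference of -14.3 percentage points ranged from -18.5 to -9.42 with 1 liver left out, smallest without TCPOBOP replicate 1. It was -7.75 among the 3 libraries with the higher background share and -25.0 among the 3 with the lower. Neither list of fragments over 1100 bp held an island in this window, but rows of these lists may be missing, as around HoxB. For HoxB the means were 98.7 ± 2.18% and 90.8 ± 11.3% (SD, n = 3 each, exact permutation p = 0.3), a difference of -7.93 percentage points. With 1 liver left out it ranged from -11.6 without TCPOBOP replicate 2 to -1.41 without TCPOBOP replicate 3. At equal covered length and with the score minimum it was -10.1. HoxA, HoxC, HoxD and the Alb window differed by less than 1 percentage point.

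**Figure D4:**
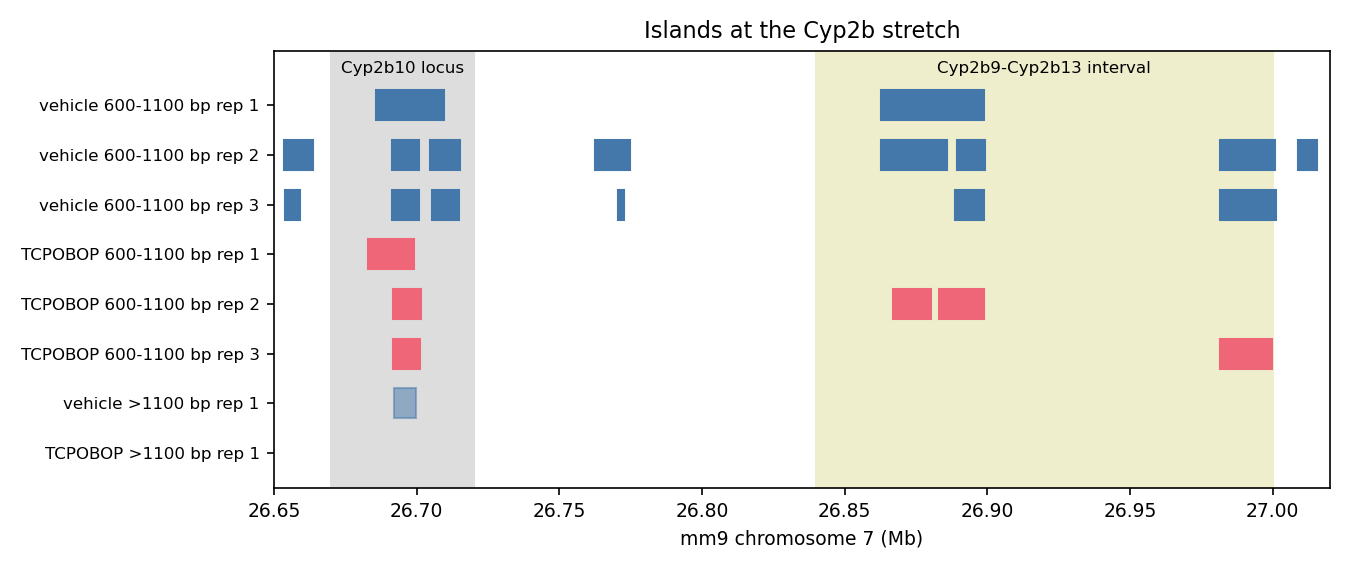
Islands (bars) of the 8 libraries along mm9 chromosome 7 (position in Mb) at the Cyp2b genes; blue is vehicle, red is TCPOBOP, paler bars are fragments over 1100 bp, and shading marks the 2 approximate windows. Each liver has an island within the Cyp2b10 window, and the part from 26705201 to 26709600 is covered in the 3 vehicle livers of 600 to 1100 bp alone. In vehicle replicate 3 the island over that part is near the lowest score of its list. The same holds for the island of TCPOBOP replicate 3 within the Cyp2b10 window.

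The share of each library's covered length that fell on a chromosome separated the treatments for chromosome 8 alone among the 20 chromosomes tested, where chance gives 10%. It took 5.46 ± 0.119% with vehicle and 5.20 ± 0.0968% with TCPOBOP (SD, n = 3 each, exact permutation p = 0.1, adjusted p = 0.667). As a percent of the chromosome's own length, 0 chromosomes separated the treatments.

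The last comparison set fragment classes of the same ChIP sample side by side, without a test because there were 2 pairs. In the vehicle liver, fragments over 1100 bp listed 17577 islands over 654 Mb, against 10057 islands over 340 Mb for 600 to 1100 bp. In the TCPOBOP liver the values were 22077 islands over 676 Mb against 13759 over 248 Mb. The longer fragments were sequenced 4.70 and 5.87 times as deeply by background reads, so class and depth were not separable. Of the territory of 600 to 1100 bp fragments, 83.2 and 85.9% lay within the islands of the longer fragments of the same ChIP sample, and 82.4 to 86.9% within those of another liver. The Jaccard index was 0.398 and 0.30 for the 2 pairs, and 0.764 between the longer fragments of the 2 livers, which differed in animal and treatment. With the 2 lists of a ChIP sample cut to the covered length of the shorter, as planned, the pairs stood at 0.445 and 0.334. With all 8 lists cut to 174 Mb, chosen after seeing the data, they stood at 0.362 and 0.291 and the longer fragments at 0.706, while at that length pairs of different livers of 600 to 1100 bp ranged from 0.350 to 0.486.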

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

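The covariate in limma, the split by background share, the cut of all 8 lists to 174 Mb and the matching of windows on the mean of the 6 livers were chosen after the data had been seen. Island number and covered length kept their direction under all alternatives chosen beforehand that were run, but among the 3 libraries with the lower background share they were 170 islands and 8.07 Mb higher with TCPOBOP; the cause was not tested. No alternative to an exact test passed 0.05, which the design rules out. Median width, 2.27 kb higher with TCPOBOP, became -3.20 kb at equal covered length, -3.20 kb among the 3 libraries with the higher background share, and ranged from -0.467 to 6.53 kb with 1 liver left out, negative without vehicle replicate 3; the cause was not tested. The Jaccard difference ranged from -0.0219 to 0.0162 with 1 liver left out, positive without TCPOBOP replicate 1 or 2; the cause was not tested. Over 13 alternatives the Cyp2b10 difference was -28.4 to -6.40 percentage points, its sign fixed in most by construction. The treatments overlapped with the score minimum and at equal covered length.

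Against 38 for vehicle and 7 for TCPOBOP, treatment-specific regions numbered 22 and 4 with the score minimum, 5 and 4 with ChIP samples merged, 118 and 19 when any overlap counted, 6 and 0 at 80%, and 239 and 49 in 10 kb bins. At equal covered length 1 was specific to vehicle. Leaving out 1 liver, which loosens the rule by construction, gave 46 to 380 for vehicle and 12 to 111 for TCPOBOP, the highest without vehicle replicate 1 and TCPOBOP replicate 3. Chromosomes that separated the treatments numbered 2 with the score minimum, 2 at equal covered length, 0 by the chromosome's own length and 2 to 7 with 1 liver left out, the last by fewer livers. limma called 0 regions under every alternative, the covariate included, except the arcsine scale, which called 1 lower region. Over all alternatives its lowest adjusted p ranged from 0.043 to 1.

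The Jaccard index of a ChIP sample's 2 libraries moved from 0.398 to 0.445 with both lists at the length of the shorter, 0.362 with all 8 lists at 174 Mb and 0.374 with the score minimum for vehicle, and from 0.30 to 0.334, 0.291 and 0.192 for TCPOBOP; the cause was not tested.

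The labels give replicate numbers without a shared animal. Deviations of same-numbered livers correlated at -0.0539, -0.0163 and 0.039, which gave no sign that the numbers pair the livers. With so few livers, each set against the mean of its own group, a weak pairing is not excluded. With a replicate block limma called 0 regions, with 361 at an unadjusted p under 0.05, and 8 chromosomes had all 3 paired differences in 1 direction. Not every liver correlated best with its own number. The promoter counts were not run. Depth limits all lists: background reads per window differ by library, and islands missing from a shallow list are not shown to be unmarked.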

Other observations

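The tests of island width, of the read threshold at Cyp2b10 and of the chromosome 2 island were chosen after the result had been seen.

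Little of chromosome X lay under islands in either treatment or fragment class. Autosomes were covered 41.5 to 432 times as densely as chromosome X in the 8 libraries, with 61 and 85 islands on X in the deeper libraries of fragments over 1100 bp, which covered 0.511 and 0.657% of it. Male cells carry fewer copies of X than of each autosome, while the background worked out for a library was the same for all its chromosomes. Low cover of X is therefore not shown to be absence of the mark. The Cyp2b9 and Cyp2b13 window held islands in 5 of 6 livers in the class of 600 to 1100 bp, TCPOBOP replicate 1 being the exception, and in 0 of the 2 deeper libraries.

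Island width crossed the treatments. Every TCPOBOP library (3 of 3) lay within the range of the vehicle libraries, so treatment alone did not sort the libraries into wide and narrow ones. That overlap was part of the pattern as picked, and a smaller effect of TCPOBOP on width is not excluded. A candidate explanation is the caller's window threshold, which has to be a whole number of reads, so that libraries with a background just under a step let more background windows pass and join more islands. Median width and the share of background windows at the threshold ranked the 8 libraries alike, apart from a tie at 24.4 kb, and the narrowest library at 14% or more was 4.40 kb wider than the widest at 12% or less. Differences in real domain width between livers remain untested.

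Less of the Cyp2b10 window lay under islands in the TCPOBOP livers. The read threshold stays open: the TCPOBOP livers were lower on both sides of the split by background share, with -6.40 percentage points on the closer side, but groups that do not overlap must keep their order in any subset. Lower total coverage cannot be told apart either, since at equal covered length the mean difference was -15.7 but TCPOBOP livers at 20 and 19.2% reached or passed the 2 vehicle livers at 19.2%. Variation between livers also stays open: 5.80% of 3465 windows with a like vehicle mean showed as large a drop without overlap, over the 5% set in advance, with a median difference of -9.07 percentage points over those windows, but matching on the mean of the 6 livers, chosen after seeing the data, gave 4.30% of 4120 windows. An effect of TCPOBOP on the mark at this gene therefore remains a hypothesis.

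The chromosome 2 island from 77808001 to 77835600 differed between livers. Its reads relative to background were worked out from the scores. They were 13.7, 7.54 and 7.54 in the vehicle livers and 18.1, 6.84 and 13.1 in the TCPOBOP livers. Of 3 TCPOBOP livers, 1 was within the vehicle range and 1 each above and below it. Livers of the same treatment differed by up to 1.82 times with vehicle and 2.64 times with TCPOBOP, which the treatment alone cannot give. A treatment effect on top of such differences is not excluded by the overlap of 3 livers with 3. After division by the HoxA island the livers of a treatment still differed by 1.92 times or more. Enrichment of the whole ChIP stays open, because 1 island stood for the whole ChIP and the division did not keep libraries of a ChIP sample together. The 2 libraries of a ChIP sample gave 13.7 and 14.5 for vehicle and 18.1 and 19.4 for TCPOBOP, at most 1.07 times apart, but after the division by HoxA they stood further apart, at 2.99 and 4.13 and at 4.06 and 5.88. A copy number that differs between outbred animals may underlie the difference between livers. It may lie at the R2d repeat, which general knowledge places on this part of the chromosome. Without input DNA it cannot be told apart from a difference in the mark itself or in enrichment of the ChIP.

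The 6 livers make 10 splits, too few for a share under 0.05. The treatments gave 45 specific regions and the highest other split 102, with 6 splits at 45 or more. That highest split set vehicle replicate 1 and TCPOBOP replicates 2 and 3 against the rest, the livers with the higher background share, but a split that crosses that share, vehicle replicates 1 and 2 and TCPOBOP replicate 1 against the rest, gave 97. limma called 0 regions for the treatments and 0 in the highest other split, so all 10 splits gave as many. At an unadjusted p under 0.05 the treatments gave 225 regions and the highest other split 902, which set vehicle replicates 1 and 2 and TCPOBOP replicate 2 against the rest. These 3 have the largest covered lengths, 340, 284 and 280 Mb against 248, 196 and 174 Mb, and 885 of the 902 regions went in 1 direction, so a difference in total coverage was not separated from it; the split by background share gave 344.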
